A study of Homo sapiens with 12 samples.

How the data were processed

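Gene expression was measured by RNA sequencing in MV3, an established human melanoma cell line. Per the labels, cells in 12-well plates were changed to RPMI medium with 1% EV-depleted serum for 3 h and then kept for 24 h with PBS (Ctrl) or with 1e10 particles per well of extracellular vesicles (EVs). The vesicles had been isolated by ultracentrifugation from THP-1 macrophages, a human monocytic leukaemia line, polarized for 48 h to an M0, M1 or M2 state. The labels do not name the polarizing agents. There were 4 groups (Ctrl, M0 EV, M1 EV, M2 EV) of 3 libraries each. The labels number the replicates but do not say whether they were separate cultures, vesicle preparations or wells, so error bars and p-values measure the spread between these samples.

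The authors prepared directional poly(A) libraries from total RNA (RNeasy Plus), sequenced on a NovaSeq X Plus. Their processing notes name STAR 2.6.1b, HOMER 4.10 and the hg38 build without giving each tool's role. Whether counting used the strand is not given in the sources used here. The deposited values are expected counts (expected_counts) for 70507 RefSeq transcripts in 12 libraries, with no normalization. Every value was a multiple of 0.5, and 51.3% of the non-zero values were not whole. Reads of exons shared by isoforms seem to be counted under each isoform, which was not tested, so transcripts of a gene were not added. One column name lacks the digit of the cell line's name and was taken as M0 EV replicate 1, the only library without a column. No other per-sample columns were present.

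Transcripts were named with the RefSeq annotation of GRCh38.p14 (69830 transcripts) and, where it lacked them, with GENCODE release 29 (326). The 351 without a name held 0.061% to 0.064% of the counts of each library and were left out. Each of the 28086 genes was represented by its transcript with the most counts over all libraries (12543 genes had more than 1), rounded to whole counts. Gene totals ranged from 9694669 to 14379469 counts per library. A count of 0 over the 3 libraries of the M1 EV group allows up to 3 counts, or 0.0967 in counts-per-million units (CPM). Floors cover counting error only, since read pairs without molecular identifiers are not independent molecules. The counts do not resolve reads shared by near-identical sequences, such as CXCL1, CXCL2 and CXCL3, the HLA class I genes, or MT-RNR1 and its nuclear copies.

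Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's default filter for the 4 groups, which left 13112 genes holding 99.91% of the gene totals. Scaling was by TMM (factors 0.993 to 1.007). A quasi-likelihood negative binomial model with 1 term per group was fitted over all 12 libraries (8 residual degrees of freedom, biological coefficient of variation 2.59%) and tested 2-sided in 6 comparisons. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p below 0.05. Fold changes are log2 values with the standard error (SE) of the model. CPM values are TMM-scaled means with the standard deviation (SD) over 3 libraries. The replicate number was not used as a block. The test was tried on simulated data made from these libraries: in the 6 comparisons it recovered 60% to 74% of genes changed 1.25-fold, 80% to 90% of those changed 1.5-fold and 92% to 98% of those changed 2-fold. Of 179 to 192 simulated calls, 12 to 16 were false. Each simulation held 50 genes changed at each size, up to 4-fold, and recovery with fewer changed genes was not measured.

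Gene lists (39, with 1051 entries and 959 different genes) were written before the data were examined. The 34 with at least 5 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Their p-values were adjusted over the 34 lists within each comparison. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance in 1 direction, were alternatives. Beside the count of genes called over all tested genes, each list has a count adjusted over the list alone.

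The rule for named genes was also fixed before the data were examined. It took, in each comparison with Ctrl, the 8 largest rises and 6 largest falls, and in each comparison between vesicle types the 5 largest of each. They had to have an adjusted p below 0.05, a mean of at least 1 CPM and groups that did not overlap, which chance gives in 10% of genes with 3 against 3 libraries. Unnamed loci, small RNA hosts, antisense and read-through names were excluded. It added up to 4 genes with the smallest adjusted p from each list described, and 15 fixed genes in each comparison with Ctrl, among them CXCL8, IL6, CCL2, CXCL10, IL1B, ICAM1, NFKBIA, TNFAIP3, MMP1, MMP3, PLAU, MITF, AXL and MKI67. A few genes that the rule takes are not reported here.

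Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no low-count filter, a mean of at least 5 CPM, the replicate number as a block, only the 2 groups compared, an adjusted p below 0.01, a fold change of at least 2, all transcripts as deposited, and leaving out each library in turn. A fit with M0 EV replicates 2 and 3 summed, and a removal of GC content and length trends per library (loess, span 0.3, 98.1% of tested genes with values), were added after seeing the data. The tests of a response shared between vesicle types used genes called in a comparison of M1 EV with the vesicle type not under test, with an absolute log2 fold change of at least 1 and a mean of at least 1 CPM. Their medians were set against 10000 random lists matched for expression in 50 bins, and shares were given 95% intervals from 2000 bootstrap draws of genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.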

Results

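RNA was sequenced from 12 libraries of MV3 melanoma cells kept for 24 h with PBS or with vesicles from M0, M1 or M2 THP-1 macrophages, 3 libraries per group. The gene totals of the Ctrl libraries were 9946621, 9694669 and 11250628 counts, those of the M0 EV libraries 12296331, 10088821 and 11366012, those of the M1 EV libraries 9763022, 11048604 and 10201843, and those of the M2 EV libraries 10207761, 14379469 and 13125546. Between 15837 and 16432 genes had a count in each library, and 13112 were tested. The first principal component of log2 CPM held 43.2% of the variance, with the M1 EV libraries at 21.95 to 23.82 and the other 9 at -9.86 to -6.01. Among these 9, Ctrl lay at -9.86 to -9.11, M0 EV at -7.49 to -6.5 and M2 EV at -6.15 to -6.01. The second component held 6.9%. Differences between 2 libraries of a group were 1.04 to 2.34 times counting noise (chi-square per degree of freedom). The lowest value was for M0 EV replicates 2 and 3, and the highest were for M0 EV replicate 1 against replicate 2 (2.02) and replicate 3 (2.34).

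**Figure D1:**
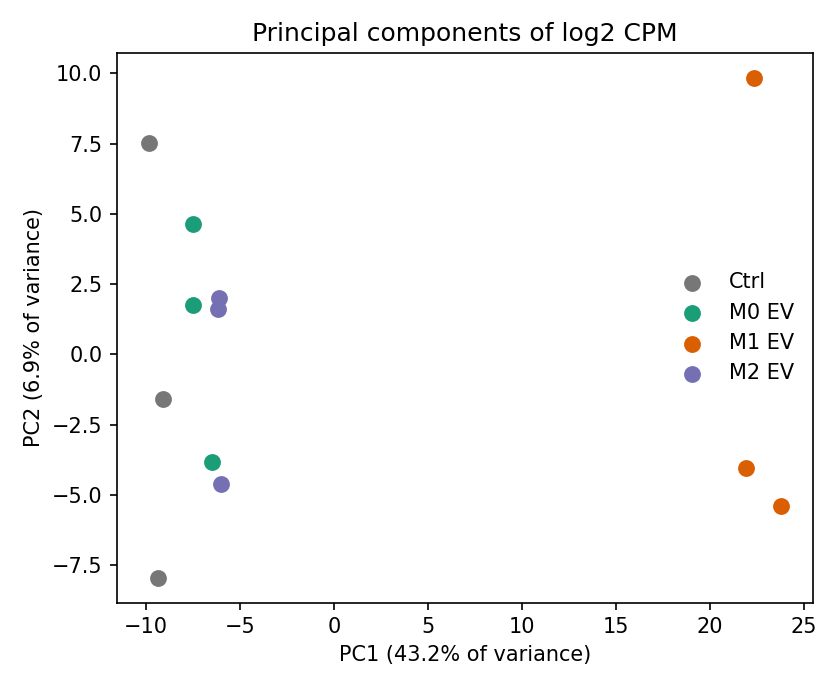
Principal components of log2 CPM over the tested genes, 1 point per library, with PC1 (43.2% of the variance) on the x axis and PC2 (6.9%) on the y axis. The 3 M1 EV libraries lie between 21.95 and 23.82 on PC1, and the other 9 lie between -9.86 and -6.01.

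The comparison of M1 EV with Ctrl asked how melanoma cells responded to vesicles of M1 macrophages, the type the study's title names. Neutrophil-attracting chemokines were among the genes with the largest rises. CXCL8 went from 1.96 ± 0.23 to 106.9 ± 4.5 CPM (SD, n = 3), a log2 fold change of 5.76 ± 0.089 (SE, adjusted p = 2.12e-36). CXCL5 went from 28.25 ± 1.75 to 342.7 ± 9.9 CPM (log2 fold change 3.60 ± 0.047, adjusted p = 1.23e-38) and CXCL1 from 12.67 ± 1.19 to 207 ± 13 CPM (4.02 ± 0.061, adjusted p = 2.12e-36). CXCL3 and CXCL2 rose by 3.46 and 3.44 on the log2 scale from levels below 1 CPM. Of the 24 genes of the chemokines list, 7 were tested. Of these, 5 rose, and 5 when adjusted over the list alone (camera adjusted p = 9.28e-08, and 0.00393 with an estimated correlation). CXCL10 had no count in any library and CCL2 had at most 4 counts in a group, so neither was tested. In GRCh38, CXCL8, CXCL1 and CXCL5 lie on chromosome 4, at 73740569 to 73743716, 73869393 to 73871308 and 73995642 to 73998677.

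In the same comparison, 24 of the 27 tested genes of the NF-kB response list rose and none fell, with the same count adjusted over the list alone (camera adjusted p = 3.85e-23, and 0.000227 with an estimated correlation). ICAM1, an adhesion receptor for leukocytes, went from 10.61 ± 0.10 to 76.57 ± 1.80 CPM (SD, n = 3; log2 fold change 2.85 ± 0.066, adjusted p = 6.54e-30). The feedback inhibitors TNFAIP3, NFKBIA and TNIP1 rose by 2.34, 1.34 and 1.00 on the log2 scale. SOD2, the mitochondrial superoxide dismutase, and BIRC3, an inhibitor of apoptosis, rose by 1.77 and 2.28. Of the 27 tested genes of the cytokines and growth factors list, 17 rose and 1 fell (18 and 1 adjusted over the list alone; camera adjusted p = 1.71e-08, and 0.00275 with an estimated correlation). IL32 went from 1.41 ± 0.18 to 32.7 ± 2.6 CPM (log2 fold change 4.51 ± 0.13, adjusted p = 2.03e-26) and IL1B from 5.08 ± 0.53 to 42.78 ± 3.54 CPM (3.08 ± 0.094, adjusted p = 5.08e-26). IL6 rose by 2.05 and CSF3, the granulocyte growth factor, by 3.31 on the log2 scale. C3, the central complement component on chromosome 19 (6677704 to 6720650), rose by 5.13 ± 0.34 (adjusted p = 3.7e-15) from 5 counts over the 3 Ctrl libraries to 186 over the 3 M1 EV libraries.

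Interferon-related lists gave different calls in M1 EV against Ctrl. Of 22 tested genes of the interferon-gamma response list, 11 rose (12 adjusted over the list alone) and none fell (camera adjusted p = 3.58e-05, and 0.0195 with an estimated correlation). They included the complement proteases C1S (log2 fold change 3.01 ± 0.22) and C1R (1.06 ± 0.12) and NLRC5, the activator of class I genes (0.70 ± 0.073). Of 20 genes of the antigen presentation class I list, 16 rose, and 16 adjusted over the list alone (camera adjusted p = 1.03e-07). That call was not kept with an estimated correlation (adjusted p = 0.0539). HLA-B went from 41.51 ± 2.64 to 82.71 ± 5.66 CPM (SD, n = 3), and the peptide transporter TAP2 rose by 0.36 on the log2 scale. The type I interferon response list was not called (adjusted p = 0.725): 6 of its 33 tested genes rose and 4 fell, also adjusted over the list alone, with a camera direction of up and a fry direction of down. IFIT2, IFIT1 and SAMD9L fell by 1.03, 0.94 and 0.66, and OAS3 rose by 0.42 on the log2 scale.

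Genes of matrix breakdown and of melanoma cell state changed in both directions in M1 EV against Ctrl. Of 31 tested matrix proteases and inhibitors, 14 rose and 10 fell, also adjusted over the list alone, and the list was not called (adjusted p = 0.134). The urokinase PLAU went from 369.8 ± 12.0 to 689.5 ± 10.7 CPM (SD, n = 3; log2 fold change 0.90 ± 0.032, adjusted p = 7.48e-24). The membrane protease MMP14 rose by 0.56, SERPINE2 by 0.60 and the collagenase MMP1 by 1.22 on the log2 scale. MMP3 rose by 1.31 ± 0.37 (adjusted p = 0.00629) from 0.586 to 1.47 CPM, a call lost with DESeq2 (adjusted p = 0.0598) and without M1 EV replicate 1 (0.0575). In the undifferentiated and invasive melanoma state list, 11 of 29 tested genes rose and 7 fell (11 and 8 adjusted over the list alone; camera direction up, adjusted p = 0.47), with a median log2 fold change of -0.0038 and a mean of 0.18. THBS1, a matrix glycoprotein, rose by 0.69, while CAV1, a component of caveolae, fell by 0.69 on the log2 scale. The receptor kinase AXL went from 1311 ± 13 to 1038 ± 29 CPM (log2 fold change -0.34 ± 0.028, adjusted p = 1.33e-12).

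Of the 27 genes of the melanocytic differentiation list, 10 were tested in these libraries. In M1 EV against Ctrl 2 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.537). GPNMB fell by 0.61 and the melanocortin receptor MC1R rose by 0.41 on the log2 scale. The other rise, of PAX3 (0.23 ± 0.079, adjusted p = 0.035), lost its call with DESeq2 (adjusted p = 0.147) and without each library of the 2 groups in turn (0.0508 to 0.124) except Ctrl replicate 3. MITF, the melanocyte master regulator, had 25 counts in Ctrl and 28 in M1 EV and was not tested. Of 21 tested YAP and TEAD targets, 12 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.000158, and adjusted p = 0.0653 with an estimated correlation). MYOF fell by 0.59, AJUBA by 0.32 and ASAP1 by 0.28 on the log2 scale. Of 19 tested TGF-beta targets, 10 rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.00137, and adjusted p = 0.0828 with an estimated correlation). PMEPA1 rose by 1.34, JUNB by 1.21 and BHLHE40 by 0.82.

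Cell cycle and heat shock genes also changed in M1 EV against Ctrl. Of 30 genes of the cell cycle G1/S list, 15 rose (19 adjusted over the list alone) and none fell (camera adjusted p = 4.21e-05, and 0.0187 with an estimated correlation). The replication factors MCM10 and MCM7 rose by 0.31 and 0.15, and UHRF1 by 0.20 on the log2 scale. Of 30 genes of the cell cycle G2/M list, 12 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 0.00252, and adjusted p = 0.107 with an estimated correlation), among them UBE2C (0.19) and CCNA2 (0.18). The proliferation marker MKI67 rose by 0.16 ± 0.052 (adjusted p = 0.0195). Its call was lost with DESeq2 (adjusted p = 0.235) and without Ctrl replicate 3 (0.229), M1 EV replicate 2 (0.126) or M1 EV replicate 3 (0.0564). Of 12 tested heat shock genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.000101, and adjusted p = 0.0828 with an estimated correlation), with the chaperones HSPE1, HSPD1 and HSP90AB1 up by 0.39, 0.32 and 0.29.

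Apoptosis, cholesterol synthesis and ribosomal protein genes were also called as lists in M1 EV against Ctrl. Of 27 tested apoptosis genes, 10 rose and 4 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.0368, and adjusted p = 0.198 with an estimated correlation). The risen genes included the inhibitors BIRC3, BIRC2 (0.61) and MCL1 (0.36) as well as the death receptor TNFRSF10B (0.45). Of 24 tested cholesterol synthesis genes, 6 fell and 2 rose (9 and 2 adjusted over the list alone). The camera adjusted p was 0.0355, and 0.0828 with an estimated correlation. MSMO1 and LSS had log2 fold changes of -0.19 and -0.15. Of 75 ribosomal proteins, 19 rose, and 19 adjusted over the list alone (camera adjusted p = 0.00439, and adjusted p = 0.743 with an estimated correlation), RPL18 by 0.13. Without Ctrl replicate 1 the adjusted p was 0.111 for apoptosis, 0.0642 for cholesterol synthesis and 0.111 for ribosomal proteins, and without M1 EV replicate 1 it was 0.0747, 0.0529 and 0.396. Apoptosis (0.064) and cholesterol synthesis (0.0649) also lost the call without M1 EV replicate 3, and cholesterol synthesis without Ctrl replicate 3 (0.0537).

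Among the largest falls in M1 EV against Ctrl were those of COL5A3, a collagen V chain (log2 fold change -2.01 ± 0.30, adjusted p = 1.16e-06), ANK1, a membrane-skeleton adaptor (-1.93 ± 0.19, adjusted p = 2.68e-10), and CPA4, a carboxypeptidase (-1.69 ± 0.10, adjusted p = 9.88e-17). CPA4 went from 22.38 ± 1.83 to 6.93 ± 0.53 CPM (SD, n = 3). TMT1B and LRRN4CL fell by 1.69 and 1.67 on the log2 scale. Of the 42 macrophage markers, 4 had enough counts to be tested, and 19 had no count in any library. CTSS, a lysosomal protease, rose by 1.98 ± 0.28 (adjusted p = 7.27e-07) and CD68 by 0.24 ± 0.050 (adjusted p = 0.000244), both also adjusted over the list alone. APOC1 (0.41 ± 0.24, adjusted p = 0.283) and CORO1A (-0.14 ± 0.27, adjusted p = 0.741) did not pass the test. In all, 3683 of 13112 genes were called, 28.1%, with 1881 higher and 1802 lower. Their median absolute log2 fold change was 0.25, and 145 changed at least 2-fold (76 higher, 69 lower).

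**Figure D2:**
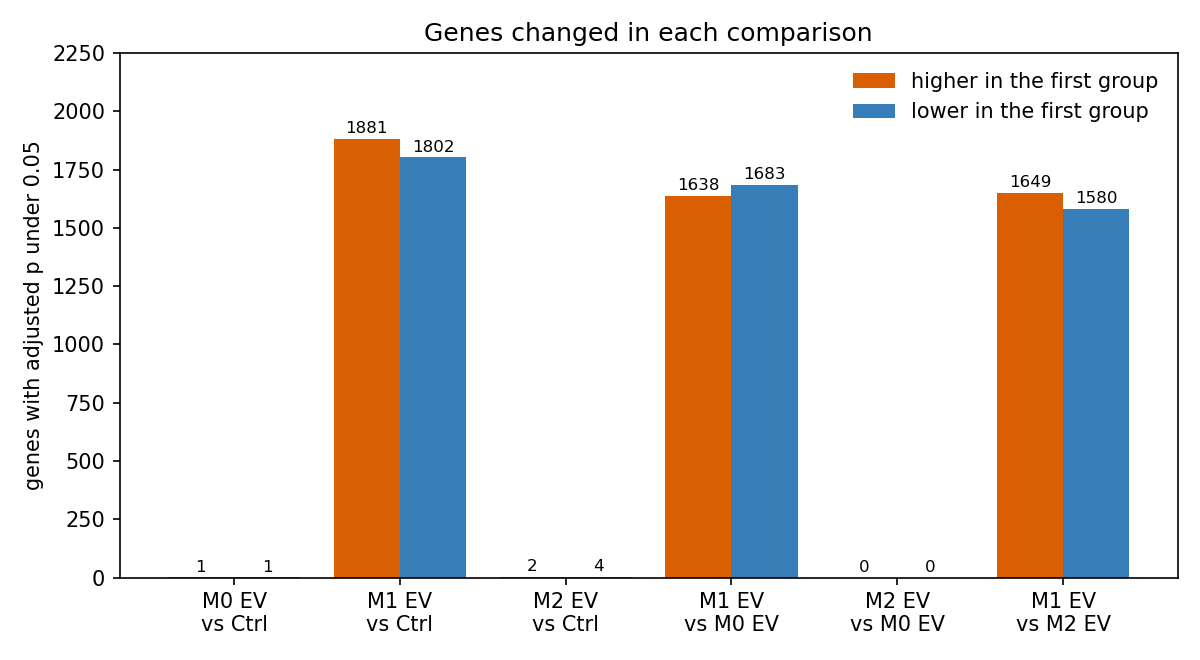
Number of genes higher and lower in each of the 6 comparisons at an adjusted p below 0.05 (edgeR, 13112 genes tested). The comparisons that include M1 EV give 3683, 3321 and 3229 genes, and the others 2, 6 and 0.

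**Figure D3:**
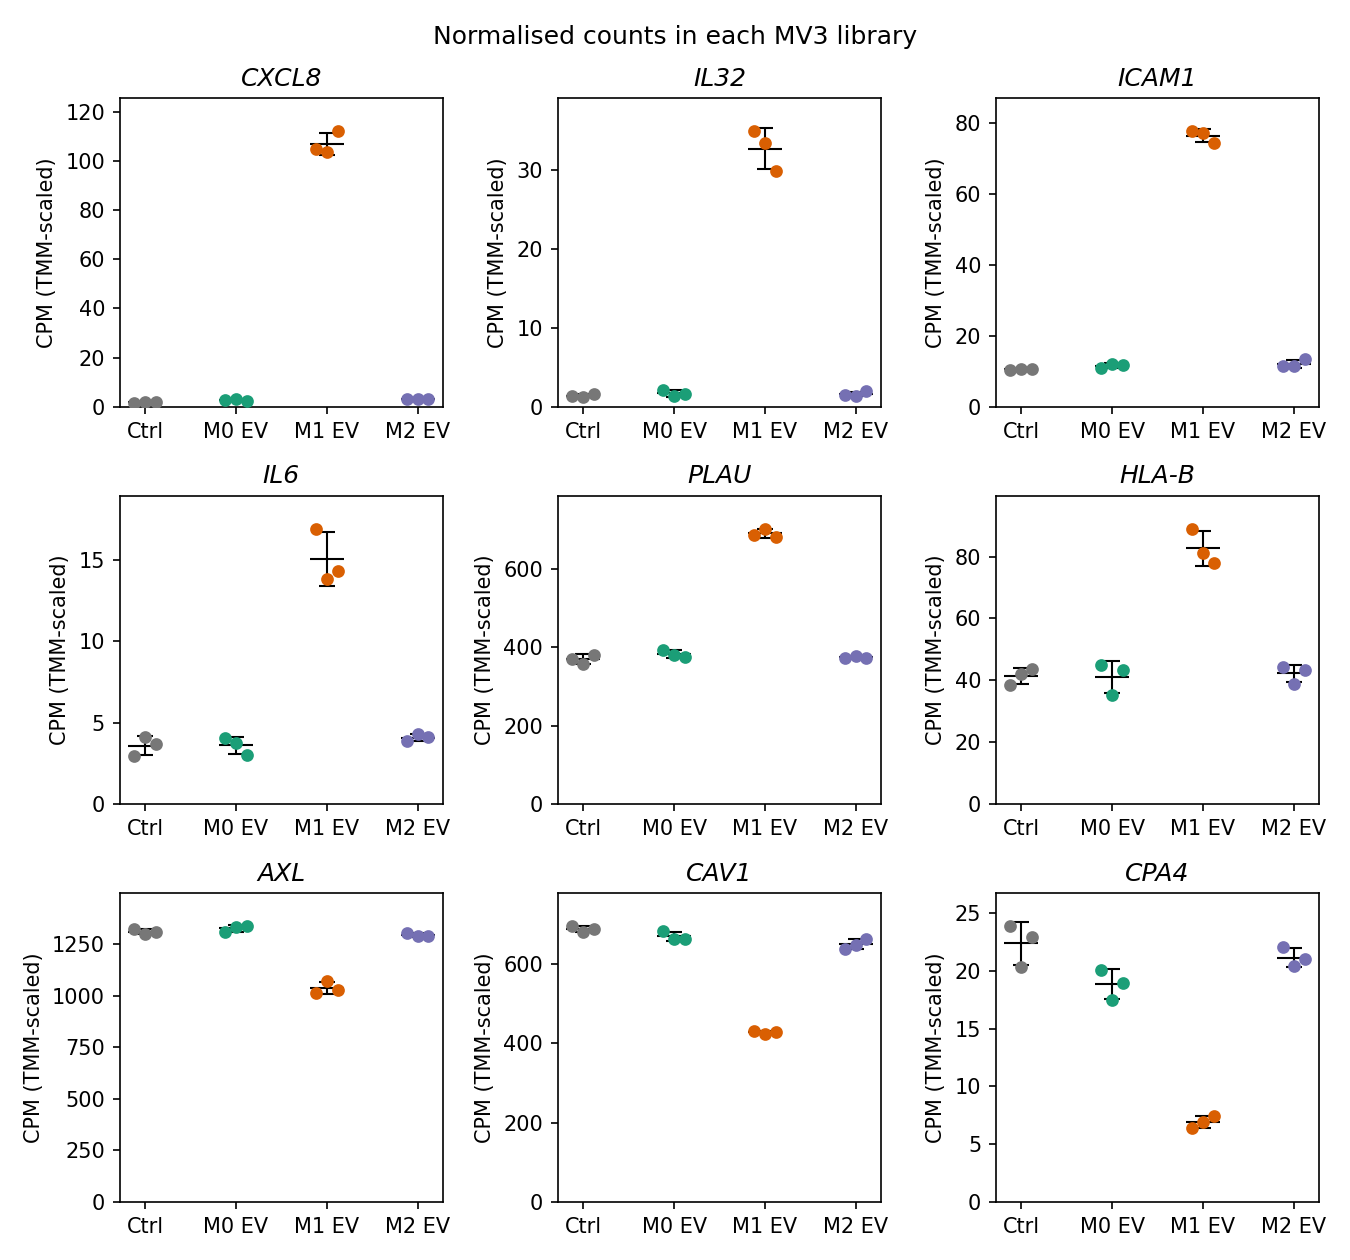
TMM-scaled CPM of 9 genes in each library (points, 3 per group), with the mean and SD of each group (lines) and a y axis from 0 in each panel. CXCL8 reaches 106.9 CPM in M1 EV against 1.96 in Ctrl, and CPA4 falls to 6.93 from 22.38.

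The comparison of M0 EV with Ctrl asked what vesicles of M0 macrophages did to the cells, and 2 genes were called. MT-RNR1, the mitochondrial 12S ribosomal RNA, went from 204.9 ± 7.9 CPM to a mean of 241.3 CPM (SD, n = 3; log2 fold change 0.23 ± 0.043, adjusted p = 0.02). UNC5B, a netrin receptor on chromosome 10 (71212570 to 71302864), went from 20.27 ± 1.40 CPM to a mean of 14.46 CPM (-0.49 ± 0.086, adjusted p = 0.02). With DESeq2 no gene was called, with adjusted p = 0.0518 for MT-RNR1 and 0.212 for UNC5B. At an unadjusted p below 0.05 there were 665 genes where 656 are expected by chance. No gene was called without Ctrl replicate 3 or M0 EV replicate 2, 1 without Ctrl replicate 2 or M0 EV replicate 3, and 87 without M0 EV replicate 1. With no low-count filter 53 genes were called, with the replicate number as a block 20, and with GC content and length trends removed (chosen after the result was seen) 22. MT-RNR1 lost its call without Ctrl replicate 2 (0.121), Ctrl replicate 3 (0.122), M0 EV replicate 2 (0.18) or M0 EV replicate 3 (0.45), and UNC5B without Ctrl replicate 1 (0.132), Ctrl replicate 3 (0.117) or M0 EV replicate 2 (0.18). With M0 EV replicates 2 and 3 summed, also chosen after the result was seen, MT-RNR1 lost its call (edgeR adjusted p = 0.182).

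No gene of any list was called over all genes in M0 EV against Ctrl, while camera called 6 lists by small shifts, none of them with an estimated correlation. The chemokines list had a median log2 fold change of 0.11 (2 genes higher adjusted over the list alone; adjusted p = 0.0112, and 0.222 with an estimated correlation), with CXCL5 at 0.25 ± 0.066 (adjusted p = 0.281) and CXCL8 at 0.52 ± 0.22 (adjusted p = 0.908). The NF-kB response list had a median of 0.054 (0 genes adjusted over the list alone; adjusted p = 0.0473, and 0.222 with an estimated correlation), with TNFAIP3 at 0.49 ± 0.18 (adjusted p = 0.746) and IRF1 at -0.13 ± 0.047 (adjusted p = 0.746). Medians were 0.034 for both cell cycle G1/S (0 genes adjusted over the list alone; adjusted p = 0.0184) and cell cycle G2/M (2 higher adjusted over the list alone; adjusted p = 0.0112), each with adjusted p = 0.222 with an estimated correlation. MKI67 stood at 0.17 ± 0.051 (adjusted p = 0.552), and passed the test with no low-count filter (0.000266) and without M0 EV replicate 1 (9.55e-05). The hypoxia and glycolysis list shifted up (median 0.033, 1 gene higher adjusted over the list alone; adjusted p = 0.0473, and 0.721 with an estimated correlation). NRF2 targets shifted down (median -0.026, 1 gene lower adjusted over the list alone; adjusted p = 0.0473, and 0.222 with an estimated correlation). Without M0 EV replicate 1 none of the 6 was called (adjusted p from 0.0514 for chemokines to 0.461 for hypoxia and glycolysis). NF-kB response also lost its call without Ctrl replicate 1 (0.216), 2 (0.118) or 3 (0.0992) or M0 EV replicate 3 (0.253), and hypoxia and glycolysis without Ctrl replicate 1 (0.201) or 2 (0.291). Cell cycle G1/S did so without Ctrl replicate 1 (0.0542) or 3 (0.0992) or M0 EV replicate 2 (0.0782), and cell cycle G2/M without the same libraries (0.0542, 0.0992 and 0.0816). NRF2 targets did so without Ctrl replicate 1 (0.0542), 2 (0.0567) or 3 (0.158) or M0 EV replicate 2 (0.101).

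The other lists of interest gave no call in M0 EV against Ctrl and no gene that passed over all genes. The adjusted p was 0.913 for cytokines and growth factors, whose median (0.014) and mean (-0.0088) differed in sign, and 0.457 for matrix proteases and inhibitors. It was 0.224 for the type I interferon response, 0.407 for melanocytic differentiation and 0.998 for the undifferentiated and invasive melanoma state, whose median (0.018) and mean (-0.0052) differed in sign. Adjusted over the list alone, 2 genes of the last list were lower and none of the other 4 lists passed. All 4 tested macrophage markers had an adjusted p of 0.999. Of the genes fixed beforehand, IL6 stood at 0.0054 ± 0.18, IL1B at -0.11 ± 0.16, ICAM1 at 0.13 ± 0.10 and NFKBIA at 0.15 ± 0.070 on the log2 scale. MMP1 stood at -0.066 ± 0.28, MMP3 at 0.10 ± 0.45, PLAU at 0.050 ± 0.032 and AXL at 0.018 ± 0.028. None of these 8 passed the test.

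The comparison of M2 EV with Ctrl asked the same of vesicles of M2 macrophages, and 6 genes were called. CXCL5 went from 28.25 ± 1.75 to 36.79 ± 0.99 CPM (SD, n = 3; log2 fold change 0.37 ± 0.063, adjusted p = 0.0101) and ESM1, a secreted proteoglycan, from 23.69 ± 1.03 to 30.47 ± 1.28 CPM (0.36 ± 0.072, adjusted p = 0.0453). UNC5B (-0.43 ± 0.083, adjusted p = 0.0354), the homeobox gene PKNOX2 (-0.34 ± 0.069, adjusted p = 0.0453), SECTM1 (-0.27 ± 0.050, adjusted p = 0.024) and the death receptor TNFRSF21 (-0.17 ± 0.034, adjusted p = 0.0453) were lower. The levels of these genes in M1 EV libraries were 342.7 CPM for CXCL5, 89.09 for ESM1, 7.06 for UNC5B, 21.2 for PKNOX2, 44.52 for SECTM1 and 190.6 for TNFRSF21. With DESeq2 CXCL5 alone passed, and for the other genes the adjusted p was 0.0815 to 0.437. With edgeR 814 genes had an unadjusted p below 0.05, where 656 are expected by chance, and with DESeq2 283. No gene was called without Ctrl replicate 1 or M2 EV replicate 3, 1 without Ctrl replicate 3, M2 EV replicate 1 or M2 EV replicate 2, and 24 without Ctrl replicate 2. With no low-count filter 31 genes were called, with only the 2 groups compared 62, and with GC content and length trends removed, an alternative chosen after the result was seen, 69. CXCL5 lost its call without Ctrl replicate 1 (0.0774), M2 EV replicate 1 (0.0514) or M2 EV replicate 3 (0.0651), and SECTM1 without Ctrl replicate 1 (0.206), Ctrl replicate 3 (0.342), M2 EV replicate 2 (0.604) or M2 EV replicate 3 (0.0651). UNC5B, PKNOX2 and TNFRSF21 each lost theirs without any 1 of the 6 libraries except Ctrl replicate 2 (0.0666 to 0.604), and ESM1 without any 1 of the 6 (0.0882 to 0.466). PKNOX2 and TNFRSF21 also lost the call with upper-quartile scaling (0.0622 for both), and PKNOX2 with limma-voom (0.0639).

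In M2 EV against Ctrl camera called 7 lists. The chemokines list rose with 1 of 7 genes called (3 adjusted over the list alone; median log2 fold change 0.15, adjusted p = 0.000547, and 0.0458 with an estimated correlation), with CXCL8 at 0.68 ± 0.20 (adjusted p = 0.365). The cell cycle G1/S list rose with no gene called, none adjusted over the list alone (median 0.043, adjusted p = 0.000511, and 0.0458 with an estimated correlation). The other 5 calls were not kept with an estimated correlation. They were NF-kB response (median 0.061, 2 genes higher and 1 lower adjusted over the list alone; adjusted p = 0.00581, and 0.0925 with an estimated correlation), cell cycle G2/M (median 0.024; adjusted p = 0.0205, and 0.338 with an estimated correlation) and ribosomal proteins (median 0.022; adjusted p = 0.0185, and 0.825 with an estimated correlation). Downward there were NRF2 targets (median -0.026, 1 gene lower adjusted over the list alone; adjusted p = 0.047, and 0.247 with an estimated correlation) and replication-dependent histones (median -0.14; adjusted p = 0.0205, and 0.197 with an estimated correlation). For cell cycle G2/M, ribosomal proteins and replication-dependent histones no gene passed, over all genes or adjusted over the list alone. Without Ctrl replicate 1 these 5 had an adjusted p of 0.0569 (NF-kB response, NRF2 targets, replication-dependent histones), 0.146 (cell cycle G2/M) and 0.795 (ribosomal proteins). Cell cycle G2/M, NRF2 targets and replication-dependent histones also lost the call without Ctrl replicate 3 (0.191, 0.155 and 0.151), M2 EV replicate 2 (0.0512, 0.265 and 0.122) or M2 EV replicate 3 (0.161, 0.0737 and 0.0737), and ribosomal proteins without M2 EV replicate 1 (0.399).

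The other lists of interest gave no call in M2 EV against Ctrl and no gene that passed over all genes. The adjusted p was 0.399 for cytokines and growth factors, 0.367 for matrix proteases and inhibitors (1 gene higher and 2 lower adjusted over the list alone) and 0.367 for the type I interferon response. It was 0.274 for melanocytic differentiation and 0.886 for the undifferentiated and invasive melanoma state. In these lists, apart from the proteases, no gene passed adjusted over the list alone. The 4 tested macrophage markers had adjusted p of 0.905 to 0.986. MKI67 stood at 0.15 ± 0.051 on the log2 scale (adjusted p = 0.533), and passed with no low-count filter (0.00317) and with only the 2 groups compared (0.0226). NFKBIA stood at 0.20 ± 0.068 (adjusted p = 0.487). Other genes fixed beforehand had mean levels in Ctrl and M2 EV of 3.61 and 4.11 CPM for IL6, 5.08 and 4.92 for IL1B, 10.61 and 12.25 for ICAM1, 3.07 and 3.68 for TNFAIP3, 1.81 and 2.10 for MMP1, 0.586 and 0.433 for MMP3, 369.8 and 373.8 for PLAU, and 1311 and 1295 for AXL, and none passed the test.

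**Figure D4:**
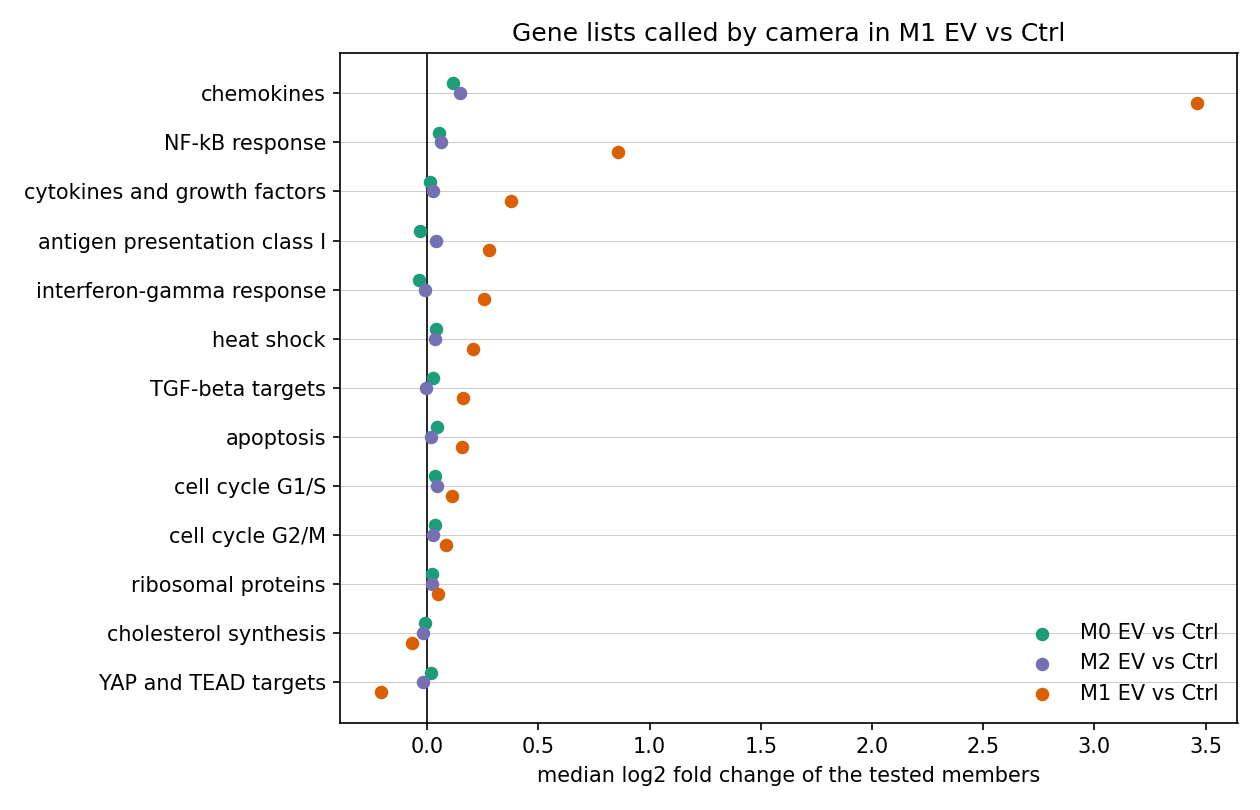
Median log2 fold change of the tested genes (x axis) of each of the 13 lists called by camera in M1 EV against Ctrl (y axis), in the 3 comparisons with Ctrl. The chemokines list is at 3.46 in M1 EV, 0.15 in M2 EV and 0.11 in M0 EV.

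All 6 genes called in M2 EV against Ctrl were called in the same direction in M1 EV against Ctrl, 2 higher and 4 lower. Independent calls would give 0.287 and 0.55. Both genes called in M0 EV against Ctrl, MT-RNR1 and UNC5B, were also called in the same direction with M1 EV (0.143 and 0.137 from independent calls). UNC5B alone was called in all 3 comparisons. Unchanged groups simulated against a shared Ctrl group, itself simulated, had 0 genes in common in 20 draws. That value leaves out the effects and the deviations of the real Ctrl libraries, while the value for independent calls leaves out the shared Ctrl libraries. Part of the excess can therefore come from the effects together with the shared Ctrl libraries. The count shared by M1 EV and M2 EV was 0 without Ctrl replicate 1, 23 without Ctrl replicate 2 and 1 without Ctrl replicate 3, 0 or 1 without an M2 EV library, and 1 with DESeq2. Without M0 EV replicate 1, M0 EV shared 25 genes with M1 EV and 14 with M2 EV, and without any other library 0 to 2 and 0 to 1.

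The direct comparison of M1 EV with M0 EV asked whether vesicles of M1 and M0 macrophages differed in what they did. The labels do not say whether the libraries of a group had separate vesicle preparations. A difference between preparations therefore cannot be told apart from polarization. C3 (log2 fold change 5.54), CXCL8 (5.24), IL32 (4.21), CXCL1 (3.76) and CXCL3 (3.58) were the most raised, C3 from 4 counts over the 3 M0 EV libraries. ANK1 (-1.58), LRRN4CL (-1.52), CAVIN2 (-1.51), a component of caveolae, and MYO5B (-1.48), a motor of vesicle transport, were among the most lowered. In all, 3321 genes were called, 1638 higher and 1683 lower, with 134 changed at least 2-fold. Of the 14 lists called, 8 were kept with an estimated correlation. In the 8, genes called higher and lower over all genes were 24 and 0 of 27 for NF-kB response, 5 and 0 of 7 for chemokines, 17 and 1 of 27 for cytokines and growth factors, 12 and 0 of 22 for interferon-gamma response, and 15 and 0 of 20 for antigen presentation class I. They were 10 and 1 of 19 for TGF-beta targets, 8 and 0 of 30 for cell cycle G1/S and 2 and 14 of 21 for YAP and TEAD targets, which was called down. Adjusted over the list alone, these 8 lists had 24 and 0, 5 and 0, 17 and 2, 14 and 0, 17 and 0, 11 and 1, 11 and 0, and 2 and 14, in that order.

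The 6 list calls of M1 EV against M0 EV that were not kept with an estimated correlation were heat shock (9 higher and 1 lower, also adjusted over the list alone; adjusted p = 0.000259, and 0.0936 with an estimated correlation), angiogenesis (9 and 5, and 10 and 5 adjusted over the list alone; adjusted p = 0.0226, and 0.0698 with an estimated correlation) and the IL-4 and IL-13 response in non-haematopoietic cells (3 and 0, also adjusted over the list alone; adjusted p = 0.0298, and 0.103 with an estimated correlation). The others were matrix proteases and inhibitors (13 and 8, also adjusted over the list alone; adjusted p = 0.0397, and 0.289 with an estimated correlation), ribosomal proteins (7 and 0, and 1 and 0 adjusted over the list alone; adjusted p = 0.0438, and 0.877 with an estimated correlation) and cholesterol synthesis (1 and 7, also adjusted over the list alone, called down; adjusted p = 0.0341, and 0.0807 with an estimated correlation). The last 4 each lost the call without M1 EV replicate 1 (0.0536 for the IL-4 and IL-13 response in non-haematopoietic cells, 0.0628 for matrix proteases and inhibitors, 0.917 for ribosomal proteins, 0.0536 for cholesterol synthesis). Without M0 EV replicate 2 the adjusted p was 0.0794 for matrix proteases and inhibitors, 0.316 for ribosomal proteins and 0.072 for cholesterol synthesis. Ribosomal proteins also lost the call without M0 EV replicate 3 (0.141), and cholesterol synthesis without M0 EV replicate 1 (0.0733) or M1 EV replicate 3 (0.0787).

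In M1 EV against M2 EV the most raised genes were CXCL8 (log2 fold change 5.08), IL32 (4.31), C3 (4.09), CXCL1 (3.73) and CXCL3 (3.64). Among the most lowered were ANK1 (-1.79), COL5A3 (-1.72), CPA4 (-1.60) and CAVIN2 (-1.48). In all, 3229 genes were called, 1649 higher and 1580 lower, with 119 changed at least 2-fold, and DESeq2 called 2098. Of the 12 lists called, the 5 kept with an estimated correlation were NF-kB response (24 of 27 higher), chemokines (5 of 7), cytokines and growth factors (17 of 27, with 2 lower), interferon-gamma response (12 of 22) and TGF-beta targets (10 of 19, with 2 lower). Adjusted over the list alone, these had 24, 5, 18 with 2 lower, 14, and 11 with 2 lower. The other 7 were, with their adjusted p and its value with an estimated correlation, antigen presentation class I (1.98e-07 and adjusted p = 0.0571), YAP and TEAD targets (down, 0.000108 and adjusted p = 0.0571), heat shock (0.000191 and adjusted p = 0.0958), cell cycle G1/S (0.0115 and adjusted p = 0.0718), angiogenesis (0.0217 and adjusted p = 0.0718), apoptosis (0.0232 and adjusted p = 0.151) and matrix proteases and inhibitors (0.0296 and adjusted p = 0.269). Genes higher and lower in these 7 were 13 and 0, 2 and 11, 9 and 1, 7 and 0, 10 and 4, 10 and 5, and 14 and 7, and adjusted over the list alone 14 and 1, 2 and 13, 10 and 1, 7 and 0, 10 and 6, 12 and 5, and 15 and 9.

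In M2 EV against M0 EV no gene was called by edgeR, with a smallest adjusted p of 0.0725 and 447 genes at an unadjusted p below 0.05 where 656 are expected by chance. DESeq2 and limma-voom also called 0, with 110 and 459 genes at an unadjusted p below 0.05. In simulated data of this comparison, 86% of genes changed 1.5-fold and 96% of genes changed 2-fold were recovered. Those data held 50 changed genes at each size up to 4-fold and nothing that sets M0 EV replicate 1 apart. The rates therefore do not show what would be recovered here if few genes differed. The antigen presentation class I list was the 1 list called, upward, with a median log2 fold change of 0.045 and no gene called (1 higher adjusted over the list alone; adjusted p = 0.00303, and 0.856 with an estimated correlation). Its call was lost without M0 EV replicate 2 (0.389) or M2 EV replicate 3 (0.184). Without M0 EV replicate 1, 36 genes were called.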

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

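The fit with M0 EV replicates 2 and 3 summed, the removal of GC content and length trends and the overlaps without a vesicle library were chosen after the result was seen. Of the named genes, the M1 EV against Ctrl results had 1371 alternative values with the same call, 17 in which the call was lost and 4 in which it was gained. Directions were compared only where the main or the alternative value was called, so uncalled values with the same call may differ in sign. For M2 EV against Ctrl these were 925, 36 and 12, for M0 EV against Ctrl 895, 10 and 6, for M1 EV against M0 EV 1199, 20 and 2, for M1 EV against M2 EV 998, 13 and 0, and for M2 EV against M0 EV 697, 0 and 0. No direction was reversed in a called value. No alternative fit of the gene counts shifted the median of all genes by more than 0.00794 (log2). Scaling between libraries keeps this shift small, so it says little about single genes. For results that moved, the cause was not tested, except where a stricter threshold or the counting of each isoform accounts for it by construction.

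Genes called in M0 EV against Ctrl (2) became 0 with DESeq2, 4 with upper-quartile scaling, 53 with no low-count filter, 20 with the replicate number as a block, 1 with the 2 replicates summed, 22 with GC and length trends removed, 0 at an adjusted p below 0.01, 0 at 2-fold and 4 over all transcripts. In M2 EV against Ctrl (6) they became 1 with DESeq2, 31 with no filter, 62 with only the 2 groups, 69 with GC and length trends removed, 0 at an adjusted p below 0.01, 0 at 2-fold and 1 over all transcripts. In M2 EV against M0 EV (0) they became 12 with no filter, 1 with the block and 3 with GC and length trends removed. The comparisons of M1 EV gave, at 2-fold, 145 against Ctrl, 134 against M0 EV and 119 against M2 EV. Over all transcripts they gave 12072, 10692 and 10558, where isoforms seem to share reads. At an adjusted p below 0.01, M1 EV gave 2190 genes against M0 EV and 2083 against M2 EV, and DESeq2 gave 2098 against M2 EV. Of the 3683 genes called in M1 EV against Ctrl, 3581 were also called with GC and length trends removed.

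The replicate numbers did not clearly pair the libraries. Residual correlations were -0.048 to 0.09 for libraries with the same number and -0.068 to 0.065 for those with different numbers. The highest were for replicate 1 of M0 EV and M1 EV (0.09) and replicate 3 of M1 EV and M2 EV (0.077). None (0) of 12 libraries correlated best with their own number in every group, Ctrl included. A weak pairing among vesicle libraries alone stays open.

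Lists called with an estimated correlation and with fry were 0 and 1 in M0 EV against Ctrl (6), 5 and 24 in M1 EV against Ctrl (13), 2 and 3 in M2 EV against Ctrl (7), 8 and 23 in M1 EV against M0 EV (14), 0 and 0 in M2 EV against M0 EV (1) and 5 and 22 in M1 EV against M2 EV (12). M0 EV against Ctrl gave 3 lists with RLE scaling and 1 with no filter, and M2 EV against Ctrl 4 with no filter. Genes shared by M0 EV and M1 EV (2) became 0 with DESeq2, 7 with the block and 0 at an adjusted p below 0.01, those shared by M0 EV and M2 EV (1) became 0, 2 and 0, and those shared by M1 EV and M2 EV (6) became 1 with DESeq2 and 0 at an adjusted p below 0.01.

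Leaving out each library in turn gave 0 to 87 genes in M0 EV against Ctrl, 0 to 24 in M2 EV against Ctrl, 0 to 36 in M2 EV against M0 EV, 3044 to 3317 in M1 EV against Ctrl, 2647 to 3118 in M1 EV against M0 EV and 2551 to 2895 in M1 EV against M2 EV. Called lists were 0 to 7, 2 to 7 and 0 to 2 in the first 3 of these. Genes shared by M0 EV and M1 EV were 0 to 25, by M0 EV and M2 EV 0 to 14 and by M1 EV and M2 EV 0 to 23. The highs came without M0 EV replicate 1 (87, 36, 25 and 14) and without Ctrl replicate 2 (24 and 23). Genes near the floor, such as C3 with 5 counts in Ctrl, rest on few counts. Of the 24 chemokines 7 had enough counts to be tested, and whether depth or absent expression left out the others was not tested.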

Other observations

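Beyond the called lists, several groups held strongly changed single genes in M1 EV against Ctrl. In the complement list 5 of 11 tested genes rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.196, direction up, median log2 fold change -0.029, mean 0.97). Besides C3, the factor CFB rose by 1.56 ± 0.25 (SE, adjusted p = 3.84e-06). In the angiogenesis list 9 of 19 rose and 6 fell, also adjusted over the list alone (adjusted p = 0.0752), with ESM1 up by 1.91, the secreted hormone STC1 by 1.08 and the co-receptor NRP2 by 0.82. Adhesion and integrins had 7 rises and 7 falls of 21 (10 and 7 adjusted over the list alone; adjusted p = 0.532), with the integrins ITGA2 and ITGA5 up by 0.66 and 0.47 and the adhesion molecule L1CAM down (-0.55). Immune checkpoints and immune ligands had 4 rises and 2 falls of 15, also adjusted over the list alone (adjusted p = 0.2): PVR rose by 0.31 and CD47, the signal against phagocytosis, by 0.20, while NT5E fell by 0.21. Of 13 replication-dependent histones 3 fell (4 adjusted over the list alone; adjusted p = 0.0959, and 0.0368 without M1 EV replicate 1), with H2BC21 and H2BC5 at -0.82 and -0.68.

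The other lists were not called in M1 EV against Ctrl. Counts of genes higher and lower were 15 and 13 of 34 for extracellular matrix (adjusted p = 0.927, median -0.071, mean 0.040), 4 and 4 of 15 for epithelial-mesenchymal transition regulators and markers (0.721), 5 and 6 of 24 for AP-1 and immediate early genes (0.849, median -0.017, mean 0.068), 7 and 6 of 21 for p53 targets (0.313) and 9 and 8 of 34 for hypoxia and glycolysis (0.532). They were 8 and 4 of 28 for the unfolded protein and integrated stress response (0.196), 3 and 5 of 20 for NRF2 targets (0.532), 6 and 2 of 37 for nuclear oxidative phosphorylation (0.532), 3 and 2 of 17 for fatty acid synthesis and lipid efflux (0.927, median -0.012, mean 0.022) and 3 and 0 of 7 for the IL-4 and IL-13 response (0.0797). Fibroblast markers had 2 and 1 of 5 (0.471) and endothelial markers 0 and 0 of 5 (0.47). Adjusted over the list alone, these were 15 and 13, 4 and 5, 6 and 6, 8 and 6, 12 and 8, 9 and 4, 3 and 5, 6 and 1, 3 and 2, 3 and 0, 2 and 1, and 0 and 0, in the same order. Metallothioneins (1 of 4 higher, 3 higher and 1 lower adjusted over the list alone) and keratinocyte markers (0 of 4) were too few to test as lists. None of the 11 T and B lymphocyte markers was tested, and the 13 mitochondrially encoded protein genes are not in the deposited table.

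The tests of whole macrophage RNA, of a response shared between vesicle types, of GC content and length, and of reads assigned to other libraries, and the use of IRF1 in the interferon-gamma test, were chosen after the result was seen. For each comparison the 6 libraries can be split in 10 ways, too few for a share under 0.05. Only 1 split, the real one, called as many genes in M1 EV against Ctrl (3683, highest other 0), M2 EV against Ctrl (6, highest other 0), M1 EV against M0 EV (3321, highest other 0) and M1 EV against M2 EV (3229, highest other 0). The other splits mix libraries of both groups, so a large group effect adds to the spread within them and itself lowers their counts. These values of 0 therefore do not measure what unrelated groups would give. In M0 EV against Ctrl 3 of 10 splits called at least the real 2, with a highest other of 87. In M2 EV against M0 EV all 10 called at least the real 0, with a highest other of 38. The split with 87 genes set Ctrl replicates 1 and 3 and M0 EV replicate 1 against Ctrl replicate 2 and M0 EV replicates 2 and 3, and that with 38 set M0 EV replicate 1 and M2 EV replicates 1 and 3 against M0 EV replicates 2 and 3 and M2 EV replicate 2. Both part M0 EV replicate 1 from replicates 2 and 3, as does a further split of M0 EV against Ctrl with 82 genes. The remaining split of M0 EV against Ctrl that parts them so called 0 genes, and those of M2 EV against M0 EV called 7 and 5. The high counts point to a structure of the samples other than the groups, for which the labels give no batch.

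For the genes raised by M1 EVs, whole macrophage RNA was examined as the source of all raised genes. The 1879 raised genes that are not macrophage markers gained 36500 CPM together, which would need a carried share of at least 3.65%. The 38 markers with fewer than 20 counts over Ctrl showed no rise (72 counts over Ctrl, 76 over M1 EV, exact binomial p = 0.805). They can hold at most 84 CPM together in that RNA. These values argue against whole macrophage RNA holding more than that as the source of all raised genes. No macrophage library shows the level of these markers in the donor cells, so a lower level stays open. Macrophage RNA carried by the vesicles for single genes, or packed selectively, stays open as well: 2 of the 4 tested markers rose, and the limit written beforehand, fewer than 5, is always met with 4 tested. Interferon-gamma carried over with the M1 vesicles may contribute and stays open: 12 of 22 tested genes of its response list were higher in M1 EV than in M0 EV (camera adjusted p = 1.68e-07, and 4.45e-06 without the 2 genes shared with the NF-kB list), the outcome written beforehand for carry-over. However, IRF1 stood at 0.07 ± 0.048 (SE, log2, adjusted p = 0.293), CXCL9, CXCL10, CXCL11, IDO1 and HLA-DRA had 0 counts in every library, and no library with added interferon shows whether MV3 cells can raise them. Tumour necrosis factor, IL-1 or lipopolysaccharide left from polarization were not tested and cannot be set against vesicle content in this design; counts over Ctrl were 5826 for TNFRSF1A, 462 for IL1R1 and 1 for TLR4, genes chosen after their values were seen.

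For the genes changed by M2 EVs, IL-4 or IL-13 carried over with the M2 vesicles stays open. None (0) of the 7 tested genes of the 17 in the IL-4 and IL-13 response list was higher in M2 EV than in M0 EV (camera adjusted p = 0.632), with a median log2 fold change of 0.031 and a highest of 0.066. This is the outcome written beforehand against carry-over, but none of the 13112 genes was called in this comparison, so the count decides nothing, and no library with added IL-4 shows whether MV3 cells respond. The other 10 genes had too few counts, and whether these cytokines were used for polarization is not in the labels.

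Genes raised at least 2-fold by M1 EVs over another vesicle type were shifted slightly in the same direction by M0 and M2 EVs. A response shared by the vesicle preparations would give such a shift. The 59 genes raised in M1 EV against M2 EV had a median log2 fold change of 0.0661 in M0 EV against Ctrl. Of these, 41 were above 0, and the highest of 10000 random lists was 0.0645. The 64 raised in M1 EV against M0 EV had 0.16 in M2 EV against Ctrl (48 above 0, highest random 0.0749). Leaving out 1 library, medians of differences in mean log2 CPM, another measure, were 0.0571 to 0.105 and 0.134 to 0.159. The lowered genes had medians of -0.0775 (38 genes) and -0.0978 (43 genes), with 0.71% and 0.06% of random lists lower still. Leaving out 1 library, theirs were -0.129 to -0.0511 and -0.132 to -0.084. In each set 1 of 10 splits, the real one, was as large, and all use the same Ctrl libraries. With GC and length trends removed the M2 EV median was still 0.16, which argues against that bias. Reads of M1 EV libraries assigned to M0 EV libraries would, alone, give 1 share for raised and lowered genes. The shares were 2.38% (95% interval 1.67 to 3.36) and 13.6% (7.56 to 19.9). For M2 EV libraries they were 3.57% (2.53 to 4.95) and 1.03% (-6.92 to 17.8) over the summed changes. As medians over genes they were 3.77% (2.77 to 5.32) and 12.4% (5.11 to 17.7). In M2 EV libraries the intervals overlap, so there a response and assigned reads cannot be told apart. The intervals come from draws of genes and leave out the spread between libraries. In M0 EV libraries the intervals do not overlap, the outcome set, after the result was seen, against assigned reads alone. As medians over genes the shares there were 1.55% (0.61 to 2.78) for raised and 10.8% (4.17 to 16.2) for lowered genes. Since these intervals also leave out the spread between libraries, they do not exclude assigned reads, alone or beside a response. Whether vesicles themselves, material isolated with them or the handling of the wells gives the shift was not tested.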
